A study of Mus musculus with 6 samples.

How the data were processed

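RNA was measured in sorted mouse bone marrow CD34⁻ KSL cells, which are lineage-negative cells carrying c-Kit and Sca-1 but not CD34 and are enriched for long-term haematopoietic stem cells (HSC). There were 6 libraries, 3 labelled EGFR-DN and 3 labelled EGFR-WT. Per the labels' protocols, oligo(dT)-primed cDNA was made from 10 ng of RNA with a SMART-Seq v4 kit, turned into libraries with Nextera XT, and read on a NovaSeq instrument as single reads of 75 bases. Nextera XT does not mark strand, so reads of a gene and of an overlapping antisense gene may be mixed.

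The authors deposited estimated counts per gene symbol, not scaled between libraries. The table holds 50763 gene symbols and 79.4% of its values are whole numbers. The submitters' processing notes name DRAGEN, DESeq2 1.40.2 and R 4.3.1, and the mouse build mm39. The role of each tool, the annotation and the strand setting are not given in the sources used here. The planned design assumed whole counts. The estimated counts were therefore rounded to whole numbers before the count tests, which otherwise stayed as planned. No row lacked a gene name, and the table held 0 columns of other samples. The table gives no coordinates and the reference used here is of an earlier mouse build (GRCm38), so no coordinates are printed. That reference served for gene names, neighbouring genes, and transcript length and base composition. Reads that could belong to near-identical copies, such as ribosomal protein pseudogenes or immunoglobulin segments, may have been split between symbols by the counting, and values of those genes are uncertain.

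Libraries were grouped by their EGFR-DN or EGFR-WT label. Total counts ranged from 24073133 to 36032428, and 3 counts in a library correspond to 0.0833 to 0.125 CPM (counts per 10⁶ counts). Such floors cover counting error only, since reads amplified by PCR are not independent molecules. No pair of libraries was a duplicate, since the smallest chi-square per degree of freedom between any pair was 16.3. The labels do not say which replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

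Genes were filtered with filterByExpr, which left 19313 genes, and scaled with the trimmed mean of M-values (TMM). EGFR-DN was compared with EGFR-WT by the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are EGFR-DN minus EGFR-WT. Their standard errors (SE) were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled and given as mean ± SD. The 41 gene lists were fixed before the data were examined. Of these, 40 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and the sex-linked list was read only as a sample check. Camera with a correlation estimated for each list and the rotation test fry, which asks whether the genes of a list move on balance in one direction, were run beside it. Of the members of all lists, 1 was not found in the table by its symbol, and 18 were matched through another symbol of the same gene.

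Genes were named by a rule fixed before the data were examined. It took Egfr, then up to 10 genes with the largest and 10 with the smallest log2 fold change among those past the threshold, with a mean of at least 4 CPM, non-overlapping groups and a name that is not a predicted-gene, clone or identifier name. Where these were fewer than 20, genes with the smallest unadjusted p that met the expression and name conditions filled the set. For each list past the threshold, up to 4 members with the smallest p were added, and up to 10 list genes past the threshold. Some genes that meet this rule are not used here. Any other gene named is said to have been chosen after its values were seen.

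Alternatives planned beforehand were size factors of DESeq2, upper-quartile scaling, library size alone, the Wald test of DESeq2 1.42.0, limma-voom, no count filter, a stricter filter of at least 50 counts in 3 libraries, the replicate number as a block, 1 surrogate variable from sva 3.50.0, removal of mitochondrial, ribosomal protein and haemoglobin genes, and each library left out in turn. Added after the data were seen were limma-voom with library quality weights, robust quasi-likelihood, removal of 8 rRNA-like genes or of 395 immunoglobulin genes, and DESeq2 without EGFR-DN replicate 3. The rRNA-like genes were Gm26917, Rn18s-rs5, Gm15564, Gm46178, Gm53756, Lars2, mt-Rnr1 and mt-Rnr2.

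The scripts were tested on counts simulated from the real means and library sizes with 200 changed genes, 100 at each fold size. The changed genes were drawn from the more abundant genes only. Each gene was given the same spread in all libraries, so no simulated library stood apart as EGFR-DN replicate 3 does. The shares recovered and falsely called need therefore not hold for the real data. For 3 EGFR-DN against 3 EGFR-WT libraries (18914 simulated genes), edgeR called 99 genes, of which 7 were false, and recovered 10% of the 2-fold and 82% of the 4-fold changes. DESeq2 (19313 genes) called 192, of which 56 were false, and recovered 44% and 92%. For 2 EGFR-DN against 3 EGFR-WT libraries, without EGFR-DN replicate 3, edgeR (19136 genes) called 181 with 19 false and recovered 71% and 91%, and DESeq2 called 228 with 48 false and recovered 83% and 97%. A simulated shift of −0.5 in 1 list, HSC genes higher with age, was called by camera at the preset correlation (adjusted p = 1.23e-15). It was not called with an estimated correlation (adjusted p = 0.145), with 0 of 39 other lists called. These counts were simulated from means and library sizes, without the real correlation between genes of a list. That correlation was estimated at 0.492 for the age list. Over lists called in the real data it ran from −0.0256 (type I interferon) to 0.830 (cytosolic ribosomal proteins). The simulation therefore cannot tell how often the preset correlation calls lists falsely in the real data, or which setting suits them. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.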

Results

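Bulk RNA sequencing was carried out on CD34⁻ KSL cells sorted from the bone marrow of mice carrying Tal1-tTA, a doxycycline-repressed activator under control of the blood stem cell gene Tal1, and TRE-EGFR-tr, its target transgene. Without doxycycline these mice made a form of the epidermal growth factor receptor that lacks the cytoplasmic kinase domain, beside the wild-type receptor (EGFR-DN, n = 3). The other mice drank water with doxycycline at 0.2 g/L and made only the wild-type receptor (EGFR-WT, n = 3). Doxycycline therefore separated the groups in every library. Total counts per library ranged from 24073133 to 36032428. EGFR-DN replicate 3 stood apart. Its 8 rRNA-like genes took 25.4% of counts against 4.71% to 6.15% in the other 5 libraries, and its ribosomal protein genes took 0.914% against 2.49% to 2.71%. Its log2 CPM values correlated with those of the other libraries across genes at no more than r = 0.928, whereas the closest pairs of the other libraries reached 0.980 (genes are not independent replicates).

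The comparison asks which transcripts of stem-cell-enriched marrow differ when the truncated receptor is made. Egfr, the gene of the receptor itself, rose in EGFR-DN. It had 6 counts in each EGFR-WT library and 4022, 4758 and 991 counts in the EGFR-DN libraries, or 0.196 ± 0.0386 CPM against 101 ± 44.7 CPM (mean ± SD, n = 3 each). The mean was 515-fold higher, with a log2 fold change of 9.01 (SE 0.53, edgeR adjusted p = 0.00981), and Egfr was higher in 3 of 3 EGFR-DN libraries. In the EGFR-WT libraries Egfr transcript was barely detected, near the floor of 3 counts, so the size of the fold is uncertain. The labels do not say whether transgene reads can be counted to Egfr, so the rise does not tell endogenous from transgenic transcripts. Egfr was the 1 gene past the threshold among 19313 tested. Egfr included, 1293 genes had an unadjusted p under 0.05, and the smallest adjusted p after Egfr was 0.524. Without EGFR-DN replicate 3 the same test called 57 genes, 46 higher and 11 lower, and DESeq2 on all 6 libraries called 99, 72 higher and 27 lower. Leaving out EGFR-WT replicate 1, 2 or 3 raised the adjusted p of Egfr to 0.286, 0.261 and 0.229, and limma-voom gave 0.253. Over all 21 alternatives it ranged from 4.69e-146 to 0.286.

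**Figure D1:**
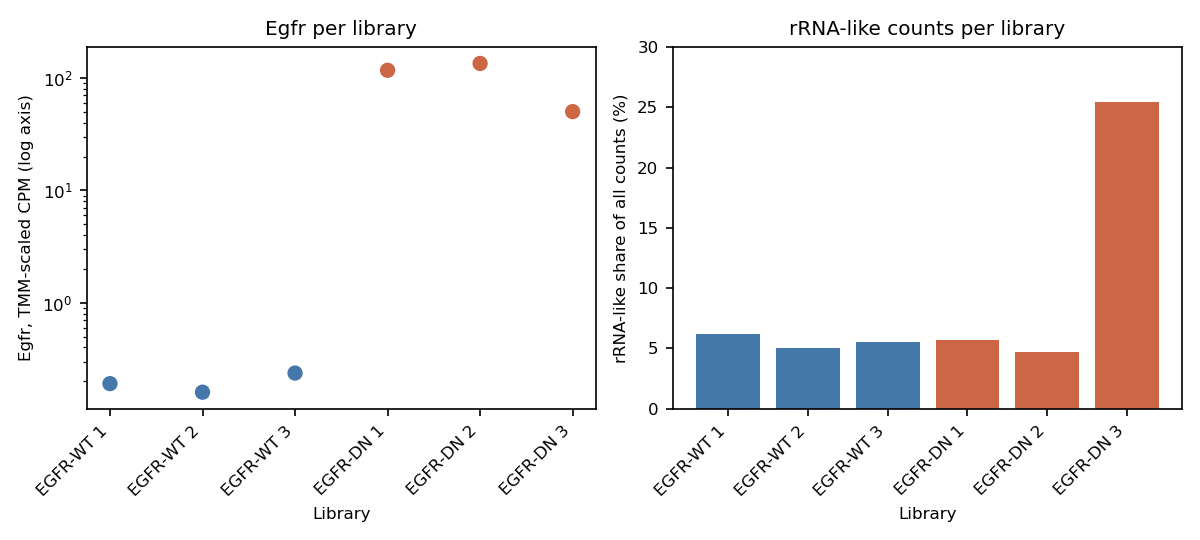
Left, TMM-scaled CPM of Egfr (log axis) in each library, 1 point per library. Right, the share of all counts in each library that fell on 8 rRNA-like genes, in percent; EGFR-WT is blue and EGFR-DN orange. Egfr was 50.3 CPM or more in each EGFR-DN library and 0.237 CPM or less in each EGFR-WT library, and the rRNA-like share was 25.4% in EGFR-DN replicate 3.

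Genes known to be more abundant in HSC of old mice were lower as a list in EGFR-DN. Of 36 tested, 32 had a log2 fold change below 0 and the median was −0.61 (camera adjusted p = 1.80e-09, but adjusted p = 0.654 with an estimated correlation). Aldh1a1, a retinaldehyde dehydrogenase, was at 56.2 ± 11.1 CPM in EGFR-DN and 111.97 ± 15.3 in EGFR-WT (SD, n = 3; log2 fold change −0.99, SE 0.20). Sult1a1, a sulfotransferase, was at 27.9 ± 10.2 against 86.6 ± 30.7 CPM (−1.64, SE 0.36). These 2 genes were lower when adjusted over the list alone (edgeR adjusted p = 0.0492 for each). Here and for the other called lists, that adjustment does not account for the list having been called on the same libraries. It is therefore not independent support for a member. Over all genes 0 members passed by edgeR (12 lower and 1 higher at an unadjusted p under 0.05). With DESeq2 the same 2 genes passed over all genes (adjusted p = 0.0153 and 0.00456). Art4 (−0.94, SE 0.26) and Tm4sf1 (−1.45, SE 0.41) did not pass either adjustment. Adjusted over the list alone without EGFR-DN replicate 3, 17 members were lower. The list medians against the EGFR-WT mean were −0.84, −0.45 and −0.39 in the EGFR-DN libraries, and 0.48, −0.11 and −0.32 in the EGFR-WT libraries. Without EGFR-WT replicate 1, the median log2 fold change was −0.30, and over the alternatives with the preset correlation the adjusted p ranged from 1.69e-14 to 0.000137.

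Genes that mark HSC identity were also lower as a list. The median of 19 tested genes was −0.22 (adjusted p = 0.000497; adjusted p = 0.672 with an estimated correlation), with 14 below 0. Procr, the endothelial protein C receptor used to sort HSC, was at 23.5 ± 8.64 CPM in EGFR-DN against 56.1 ± 16.7 in EGFR-WT (log2 fold change −1.25, SE 0.33). Esam, a junctional adhesion protein, was at 50.3 ± 5.95 against 82.8 ± 8.20 CPM (−0.72, SE 0.16), and Ctnnal1, a catenin-like protein, at 25.9 ± 3.06 against 42.5 ± 8.06 CPM (−0.71, SE 0.18). These 3 were lower when adjusted over the list alone (edgeR adjusted p = 0.0388 for each), which again leaves the choice of the list out of account. Over all genes 0 members passed by edgeR or DESeq2 (4 at an unadjusted p under 0.05 by edgeR). The retinoic acid receptor gene Rarb had a log2 fold change of −1.45 (SE 0.46) and did not pass. The list median was −0.75 and −0.37 in EGFR-DN replicates 1 and 2 and 0.07 in the rRNA-rich replicate 3. It was 0.31, −0.09 and −0.14 in EGFR-WT replicates 1 to 3, so the groups overlapped. The median log2 fold change moved to −0.60 without EGFR-DN replicate 3, where 10 members were lower adjusted over the list alone, and to −0.34 without EGFR-WT replicate 2. It moved to −0.13 without EGFR-DN replicate 1, where the call was lost (camera adjusted p = 0.199, in a range from 6.34e-11 to 0.199 over alternatives).

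Genes of multipotent and lymphoid-primed progenitors were higher as a list in EGFR-DN. Of 13 tested, 12 lay above 0, with a median of 0.97 (adjusted p = 1.02e-07; adjusted p = 0.632 with an estimated correlation). Flt3, a cytokine receptor gained as HSC become multipotent progenitors, was at 189 ± 30.3 CPM against 107 ± 13.5 (log2 fold change 0.82, SE 0.19). Satb1, a chromatin organiser of lymphoid priming, was at 104 ± 28.5 against 50.7 ± 7.49 CPM (1.04, SE 0.23). The recombinase gene Rag2 was at 8.21 ± 1.25 against 3.64 ± 0.949 CPM (1.17, SE 0.27). Adjusted over the list alone 7 members were higher, these 3 among them. Over all genes 0 passed by edgeR (8 at an unadjusted p under 0.05), and Satb1 and Rag2 passed by DESeq2 (adjusted p = 0.0459 and 0.0385). Every EGFR-DN library lay above every EGFR-WT library in list median, at 1.23, 0.72 and 0.65 against at most 0.20. Without EGFR-DN replicate 3 the median was 0.91, and 11 members were higher adjusted over the list alone.

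Myeloid lists were higher as well. The neutrophil granule list had a median of 1.497, with 12 of 12 genes above 0 (adjusted p = 7.45e-06; adjusted p = 0.632 with an estimated correlation). Mpo, the myeloperoxidase gene and the most abundant member, was at 854 ± 353 CPM against 340 ± 84.5 (log2 fold change 1.33, SE 0.34), and highest in EGFR-DN replicate 3, at 1261 CPM. The calgranulin gene S100a8 (1.67, SE 0.47) reached only 2.73 ± 1.01 CPM and Fcnb (1.80, SE 0.50) 0.811 ± 0.308 CPM. These 3 passed adjusted over the list alone, and Ngp (2.84, SE 0.98) did not. Over all genes 0 members passed by edgeR (7 at an unadjusted p under 0.05), and Mpo passed by DESeq2 (adjusted p = 0.0321). With the stricter filter 5 of the 12 genes were left, the others averaging at most 2.73 CPM in either group, and the median was 0.98 (adjusted p = 0.0276, the highest over its alternatives, with a lowest of 3.85e-12). The monocyte, macrophage and dendritic cell list had a median of 0.96, with 10 of 12 genes above 0 (adjusted p = 0.000591; adjusted p = 0.649 with an estimated correlation). Adjusted over the list alone 6 of its members were higher, with 0 over all genes by edgeR and 1, Irf8, by DESeq2 (adjusted p = 0.0380). Irf8, a transcription factor of monocytes and dendritic cells, was at 50.2 ± 14.7 CPM against 21.6 ± 5.08 (1.22, SE 0.28). The other named members were Cx3cr1 (1.34, SE 0.34), Ly6c2 (0.70, SE 0.19) and Ly86 (1.43, SE 0.45). The list medians were lower in EGFR-DN replicate 3 than in the other EGFR-DN libraries, with medians of 0.58 and 0.25 against at least 1.36 and 0.77. Without EGFR-DN replicate 1 the monocyte list had a median of 0.61, and with the stricter filter 0.60 over 10 genes (adjusted p = 0.0260 and 0.00246, the former the highest over its alternatives, with a lowest of 4.15e-06).

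**Figure D2:**
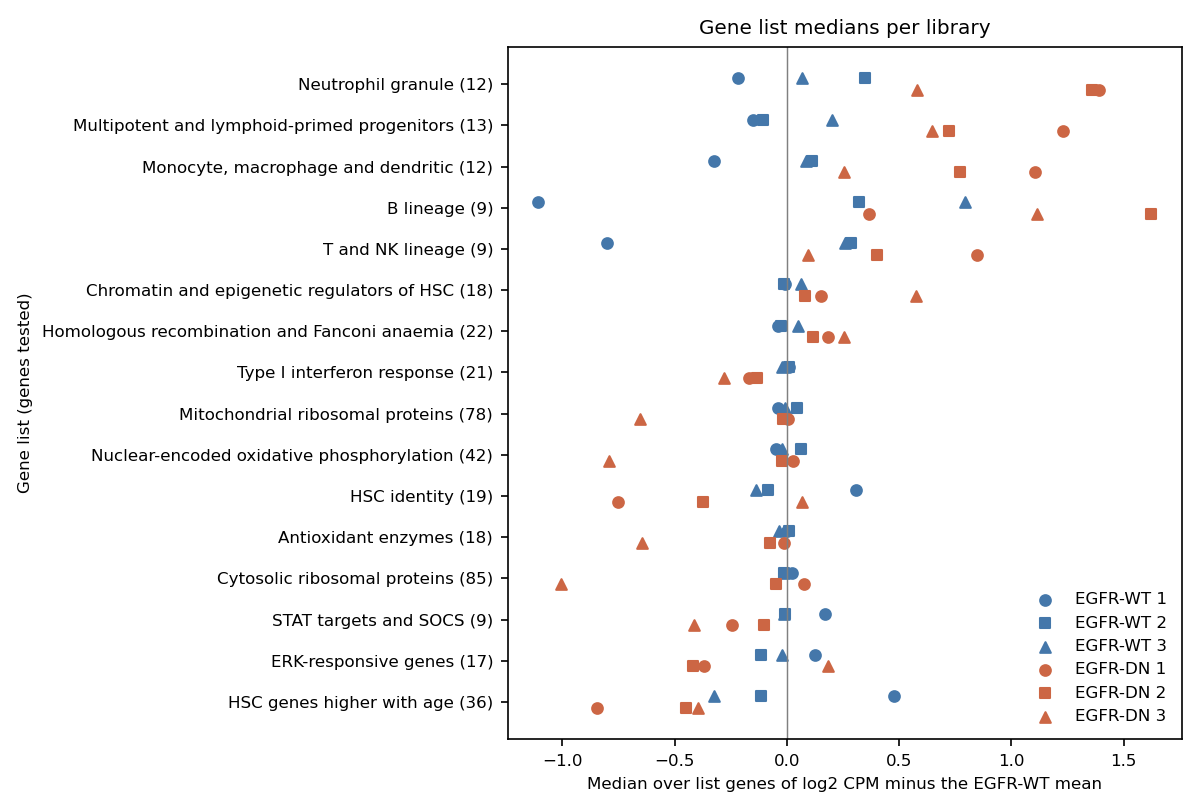
Each row is a gene list past the camera threshold, with its number of tested genes. Points give, per library, the median over list genes of log2 CPM minus the EGFR-WT mean; blue is EGFR-WT, orange EGFR-DN, and circles, squares and triangles are replicates 1, 2 and 3. The progenitor list separates the groups in every library, whereas the cytosolic ribosomal protein list is at −1.005 in EGFR-DN replicate 3 and between −0.05 and 0.08 in the other 5 libraries.

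Lymphoid lists followed EGFR-WT replicate 1 in part. The B lineage list had a median of 0.79, with 9 of 9 genes above 0 (adjusted p = 0.000519; adjusted p = 0.672 with an estimated correlation). Its named members were the signalling adaptor Blnk (1.405, SE 0.37), the B cell receptor component Cd79a (1.34, SE 0.54), and the transcription factor Ebf1 (0.66, SE 0.29). Over all genes 0 members passed by edgeR or DESeq2 (3 at an unadjusted p under 0.05 by edgeR), and 0 passed adjusted over the list alone. Immunoglobulin transcripts took 0.406% of counts in EGFR-WT replicate 1 and between 1.51% and 4.47% in the other 5 libraries, and the B lineage median was −1.11 in that library. The B lineage median was 0.32 and 0.79 in EGFR-WT replicates 2 and 3, and 0.37, 1.62 and 1.12 in EGFR-DN replicates 1 to 3, so the groups overlapped. Without EGFR-WT replicate 1 the median log2 fold change was 0.36, and without EGFR-WT replicate 3 it was 1.23, with an adjusted p between 2.88e-06 and 0.0410 over alternatives. The T and NK cell list had a median of 0.36 (adjusted p = 0.0394; adjusted p = 0.672 with an estimated correlation), with Cd4 at 1.39 (SE 0.46) and Nkg7 at 0.64 (SE 0.23), and with Lck (0.57, SE 0.36) and Il2rb (0.52, SE 0.60). Without EGFR-WT replicate 1 its median turned to −0.06 (adjusted p = 0.722). It also missed the threshold without EGFR-DN replicate 1 (median 0.22, adjusted p = 0.371) or 2 (adjusted p = 0.102), and its median was 0.55 without EGFR-DN replicate 3. Its adjusted p ranged from 0.00672 to 0.722 over alternatives. The T and NK list medians against the EGFR-WT mean were 0.85, 0.40 and 0.09 in EGFR-DN replicates 1 to 3. They were −0.80, 0.29 and 0.26 in EGFR-WT replicates 1 to 3, so the groups overlapped.

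ERK-responsive genes were lower as a list, with a median of −0.28 and 13 of 17 below 0 (adjusted p = 0.0110; adjusted p = 0.649 with an estimated correlation). Dusp6, a phosphatase induced by ERK that acts back on it, was at 48.2 ± 9.60 CPM against 76.7 ± 7.15 (log2 fold change −0.67, SE 0.18). The ERK pathway inhibitor Spred1 was at −0.40 (SE 0.15) and the transcription factor Etv4 at −1.21 (SE 0.47), while Dusp5, another ERK phosphatase, was at 0.77 (SE 0.21). Adjusted over the list alone 0 members passed. Without EGFR-DN replicate 3, the list median was −0.40, and 7 members were lower and 1 higher adjusted over the list alone. The list median was 0.18 in replicate 3 and −0.37 and −0.42 in EGFR-DN replicates 1 and 2. The call was lost without EGFR-DN replicate 1 (adjusted p = 0.189) or replicate 2 (adjusted p = 0.112) and with the stricter filter (adjusted p = 0.0665), in a range from 4.15e-06 to 0.189 over alternatives. Among ERBB receptors and ligands, Egfr passed and the other 8 tested members did not, and the list did not pass (median 0.16, adjusted p = 0.624; median −0.08 without EGFR-DN replicate 3).

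Cytokine and interferon lists showed small shifts. STAT targets and SOCS genes had a median of −0.28, with 7 of 9 below 0 (adjusted p = 0.0394; adjusted p = 0.632 with an estimated correlation). They included the cytokine feedback genes Socs2 (−1.01, SE 0.37) and Cish (−0.72, SE 0.35) and the kinase genes Pim3 (−0.29, SE 0.17) and Pim1 (−0.27, SE 0.16). Type I interferon response genes had a median of −0.15, with 16 of 21 below 0 (adjusted p = 0.0361; adjusted p = 0.632 with an estimated correlation). Ifit1, an antiviral RNA-binding protein gene, was at 12.7 ± 0.155 CPM against 19.99 ± 2.91 (−0.66, SE 0.17). Its relative Ifit3 was at −0.80 (SE 0.29), Zbp1 at −0.48 (SE 0.28) and Isg20 at −0.24 (SE 0.14). Adjusted over either list alone, 0 members passed. The STAT list missed the threshold without EGFR-DN replicate 1 (adjusted p = 0.199) or EGFR-WT replicate 3 (adjusted p = 0.0705) and with library size alone (adjusted p = 0.0515), and the interferon list without EGFR-DN replicate 1 (0.128), EGFR-DN replicate 2 (0.133) or EGFR-WT replicate 2 (0.0597). Both lists missed it with the stricter filter (adjusted p = 0.0566 each). Over alternatives the adjusted p ranged from 0.0161 to 0.199 for the STAT list and from 0.00680 to 0.133 for the interferon list.

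Genome maintenance and chromatin lists were higher. Homologous recombination and Fanconi anaemia genes had a median of 0.14, with 17 of 22 above 0 (adjusted p = 0.0272; adjusted p = 0.632 with an estimated correlation). Fancd2 was at 21.6 ± 2.86 CPM against 15.7 ± 0.852 (0.46, SE 0.16), beside Fancm (0.72, SE 0.28; 0.34 without EGFR-DN replicate 3), Fanca (0.69, SE 0.28; 0.31 without it) and Fanci (0.35, SE 0.15), and 0 members passed adjusted over the list alone. This call was lost without EGFR-DN replicate 1 (adjusted p = 0.233) or EGFR-WT replicate 2 (adjusted p = 0.0597), with library size alone (median 0.02, adjusted p = 0.0668) and with no filter (adjusted p = 0.0812). Over alternatives the adjusted p ranged from 0.00680 to 0.233. Non-homologous end joining genes had a median of 0.06 over 15 genes (−0.07 without EGFR-DN replicate 2) and did not pass (adjusted p = 0.785). Chromatin and epigenetic regulators had a median of 0.26 over 18 genes (adjusted p = 0.0279; adjusted p = 0.672 with an estimated correlation). Satb1, which is also in the progenitor list, was the 1 member higher adjusted over the list alone (adjusted p = 0.0492). The methylcytosine dioxygenase genes Tet1 (0.97, SE 0.47), Tet2 (0.85, SE 0.38) and Tet3 (0.91, SE 0.42) did not pass, and without EGFR-DN replicate 3 they were at 0.17, 0.25 and 0.22. The chromatin median was 0.58 in EGFR-DN replicate 3 and 0.15 and 0.08 in the other EGFR-DN libraries, and the call was lost without replicate 3 (median 0.11, adjusted p = 0.0726) or EGFR-WT replicate 2 (adjusted p = 0.0507), in a range from 0.0116 to 0.121 over alternatives.

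**Figure D3:**
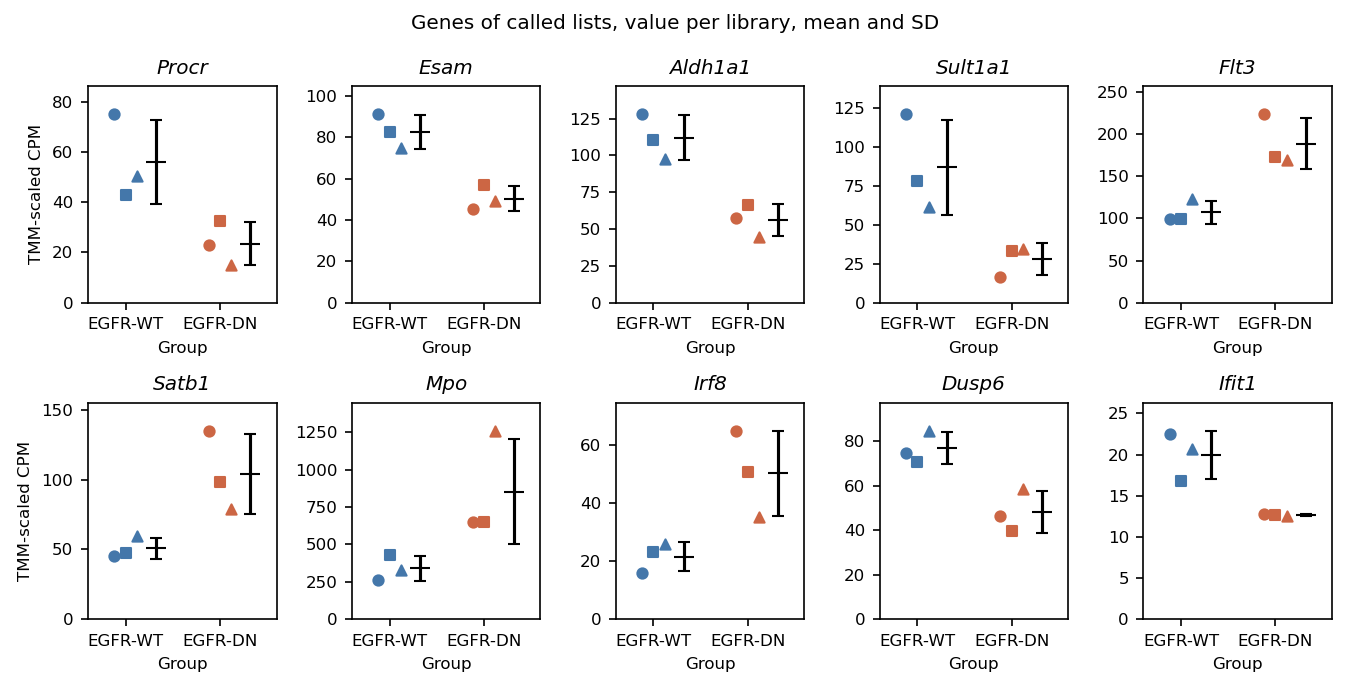
TMM-scaled CPM per library of 10 genes from lists past the camera threshold, with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD (n = 3). The groups do not overlap in any of the 10 genes, although none of them passed the adjustment over all genes by edgeR (Mpo, Irf8, Satb1, Aldh1a1 and Sult1a1 passed by DESeq2); Mpo was at 854 CPM in EGFR-DN and 340 CPM in EGFR-WT on average.

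Protein synthesis and respiration lists were lower through 1 library, and the antioxidant list largely so. Cytosolic ribosomal proteins had a median of −0.25 (85 genes, adjusted p = 1.02e-07), mitochondrial ribosomal proteins −0.19 (78 genes, adjusted p = 1.13e-05), nuclear-encoded oxidative phosphorylation −0.22 (42 genes, adjusted p = 7.14e-05) and antioxidant enzymes −0.22 (18 genes, adjusted p = 0.0110). With an estimated correlation the adjusted p was 0.771 for the first 3 lists and 0.754 for the antioxidant list. In EGFR-DN replicate 3, which had 25.4% rRNA-like counts, the 4 medians were −1.005, −0.65, −0.79 and −0.64, whereas in EGFR-DN replicates 1 and 2 they lay between −0.08 and 0.08. Without replicate 3 they were 0.01, −0.01, 0.0044 and −0.06, and none passed (adjusted p = 0.577, 0.588, 0.952 and 0.111). The lowest adjusted p over alternatives were 6.59e-15, 1.64e-08, 5.21e-08 and 0.00310, and the highest 0.644, 0.588, 0.952 and 0.144. Without EGFR-DN replicate 1, which gives replicate 3 more weight, they were −0.46, −0.31, −0.37 and −0.32, and without replicate 2 the mitochondrial ribosomal protein median was −0.30, with −0.34 for both oxidative phosphorylation and antioxidant enzymes. The members with the smallest p included Mrps6 (−0.49, SE 0.24), Cox7a2 (−0.29, SE 0.24) and the peroxiredoxin Prdx4 (−0.51, SE 0.22), while Hmox1, which encodes haem oxygenase, was at 1.13 (SE 0.45). Without EGFR-DN replicate 3, 4 antioxidant members were lower and 2 higher adjusted over the list alone. Prdx4 was then at −0.30 (SE 0.09), so some members of that list moved without replicate 3.

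The other lists did not pass, and of the 24 lists not called 17 had a median of the other sign in at least 1 alternative. Among cell types, the erythroid list had a median of 0.31 (adjusted p = 0.0811), the endothelial and stromal list 0.20 (0.772), the mast cell, basophil and eosinophil list −0.13 (0.720), and the megakaryocyte and platelet list −0.07 (0.933, with a mean of 0.05). Cell cycle lists were at 0.09 for G1/S and DNA replication (adjusted p = 0.238), −0.02 for G2/M and mitosis (0.933, with a mean of 0.07), −0.28 for CDK inhibitors (0.752) and 0.05 for quiescence regulators (0.807). Stress and death lists were at −0.10 for p53 targets (0.483), 0.14 for the BCL2 family (0.298), 0.02 for the ATF4 response (0.586, with a mean of −0.08) and 0.03 for the unfolded protein response (0.664). Metabolic lists were at −0.12 for glycolysis and hypoxia (0.680), 0.09 for cholesterol and fatty acid synthesis (0.405), 0.14 for mitochondrially encoded proteins (0.936), −0.12 for autophagy and lysosome (0.300) and −0.11 for MYC and ribosome biogenesis (0.651). Immediate early genes (0.05, adjusted p = 0.772), NF-kappaB and inflammatory genes (−0.08, 0.720), antigen presentation (−0.13, 0.181), adhesion, homing and polarity (0.24, 0.0937) and TGF-beta and BMP targets (0.05, 0.944) also did not pass. Without EGFR-DN replicate 3, the camera test called 4 of these lists: G1/S and DNA replication (median 0.17, adjusted p = 6.36e-05), the unfolded protein response (0.21, adjusted p = 0.0187), mitochondrially encoded proteins (−0.14, adjusted p = 0.0106) and adhesion, homing and polarity (0.03, adjusted p = 0.0471). With an estimated correlation all 4 missed the threshold, at adjusted p = 0.678, 0.836, 0.633 and 0.519. The erythroid list was called without EGFR-WT replicate 3 (0.48, adjusted p = 0.0340) or EGFR-DN replicate 2 (0.45, adjusted p = 0.0209), and antigen presentation without EGFR-WT replicate 1 (−0.21, adjusted p = 0.0361). Removal of mitochondrial, ribosomal protein and haemoglobin genes also called the erythroid list (0.45, adjusted p = 0.0283). That removal took the haemoglobin genes out of the erythroid list itself, so this median is over fewer than the 15 genes of the main test. G1/S and DNA replication was called with 1 surrogate variable (0.13, adjusted p = 0.0116) and with library quality weights (0.15, adjusted p = 0.00199), and adhesion with the stricter filter (0.27, adjusted p = 0.0482). An estimated correlation was not run in these alternatives, and on all 6 libraries it gave adjusted p = 0.716 for the erythroid list, 0.771 for antigen presentation, 0.780 for G1/S and 0.632 for adhesion.

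Of the 24 medians, 11 changed sign without EGFR-DN replicate 3. The endothelial and stromal median became −0.29 (and 0.73 without EGFR-WT replicate 2), that of CDK inhibitors 0.05, mast cell, basophil and eosinophil genes 0.13, and megakaryocyte and platelet genes 0.04. Quiescence regulators were then at −0.10, G2/M and mitosis at 0.03, immediate early genes at −0.05, TGF-beta and BMP targets at −0.09 and the ATF4 response at −0.04.

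Below the threshold, the genes with the smallest p included myeloid, signalling and other genes with non-overlapping groups. None of them passed over all genes by edgeR in all 6 libraries (adjusted p between 0.524 and 0.614), and no test asked whether they share a function. By DESeq2 on the same libraries every gene named in this paragraph passed, with an adjusted p from 1.79e-05 (Rasa4) to 0.00908 (Fgd2). The genes were chosen for a small edgeR p on the same counts, so this is not independent support. In the simulation with 3 libraries per group, 56 of the 192 DESeq2 calls were false. That simulation had no outlying library such as EGFR-DN replicate 3, so the share of false calls here is not known. The named genes higher in EGFR-DN included Rasa4, a Ras GTPase-activating protein, at 46.7 ± 2.66 against 22.5 ± 1.09 CPM (log2 fold change 1.05, SE 0.13). Itgam, which encodes CD11b, was at 58.5 ± 10.0 against 24.4 ± 4.62 CPM (1.26, SE 0.21), and the myeloid lectin gene Cd33 at 10.4 ± 2.56 against 3.44 ± 0.493 CPM (1.6, SE 0.26). The interleukin 1 receptor gene Il1r1 (1.02, SE 0.16), the peptidylarginine deiminase gene Padi2 (1.56, SE 0.22) and the PDGF receptor gene Pdgfrb (1.03, SE 0.18) had values in the same direction, as did Haao (1.21), Tent5a (1.27), Pou2f2 (0.96), Fgd2 (0.80), Themis2 (1.34) and Kcng1 (1.75). On the other side were Slfn2, a Schlafen family gene, at 10.6 ± 2.28 against 30.5 ± 5.93 CPM (−1.53, SE 0.23), and the transcription factor Klf9 at 43.0 ± 4.301 against 78.1 ± 8.19 CPM (−0.86, SE 0.15). Iigp1c (−1.32), Abcg3 (−1.37), Tmem158 (−1.601) and the basophil protease gene Mcpt8 (−1.34) were lower in value too. Across all genes the groups did not overlap in 17.9%. Chance gives 10% on average over all splits of the libraries, but genes are correlated and the share in the other splits was not computed. The 17.9% alone therefore does not show an excess.

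Of the 40 lists, camera called 16 at the preset correlation, 7 higher and 9 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.632 and 1 list, neutrophil granule, had an unadjusted p under 0.05 (0.0216). Fry called 0 lists, with a smallest adjusted p of 0.0905 for the interferon list and 7 lists at an unadjusted p under 0.05. Without EGFR-DN replicate 3 camera called 15 lists, 11 of them among the 16, and the smallest adjusted p with an estimated correlation was 0.286.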

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

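The library quality weights, robust fit, rRNA-like and immunoglobulin removals and DESeq2 without EGFR-DN replicate 3 were chosen after seeing the data. The count of genes past the threshold was 1 (Egfr) at first and 1 under every change of scaling, filter, gene set, surrogate variable, robust fit and replicate block. It became 99 with the DESeq2 Wald test (72 higher, 27 lower), 0 with limma-voom (0 higher; 1187 at an unadjusted p under 0.05), 188 with library quality weights (145 higher, 43 lower) and 845 with DESeq2 without EGFR-DN replicate 3 (472 higher, 373 lower). Leaving out 1 library gave 0 to 57 genes, 0 to 46 higher and 0 to 11 lower, with 57 reached only without EGFR-DN replicate 3, and 21 of these 57 were shared with the 99 of DESeq2. The Egfr log2 fold change was 8.79 with limma-voom, where it missed the threshold (adjusted p = 0.253), and 8.73 to 9.33 over the left-out libraries, where leaving out any EGFR-WT library ended the call (edgeR, 0 genes; 539, 725 and 852 at an unadjusted p under 0.05). Fewer EGFR-WT libraries estimate the spread there, and other causes were not tested. The count of lists was 16, fell to 0 with an estimated correlation and to 0 by fry, and ranged from 10 (without EGFR-DN replicate 1) to 16 over the left-out libraries. Over the left-out libraries the median of list Cytosolic ribosomal proteins ranged from −0.455 to 0.0139 and that of list Nuclear-encoded oxidative phosphorylation from −0.37 to 0.0044, both reversed without EGFR-DN replicate 3. The median of list T and NK lineage ranged from −0.0613 (reversed, without EGFR-WT replicate 1) to 0.550. The cause of each was not tested beyond the library named. The age, progenitor, neutrophil, B lineage and monocyte lists, 5 in all, passed in every alternative with the preset correlation. The limma-voom and robust alternatives use the same voom values as the main list test. Their list p-values were bound to repeat it and add no support. Library size alone moved the median of all genes to −0.10, against 0.01 with TMM. The 82 other named genes kept their direction in all 1712 alternative values, and passed in 118 of them. They had been chosen for a small p in these same libraries, so their constant direction is not independent support.

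No sign was seen that the replicate numbers pair the samples, but 3 libraries per group cannot exclude it, and the labels do not say what the numbers share. Same-numbered libraries correlated in their deviations at −0.02, 0.05 and 0.06, against −0.09 to 0.08 for libraries of unlike number. With the replicate block 1 gene passed, Egfr at 8.96 (adjusted p = 0.0133), and 12 lists. The 4 calls it ended were homologous recombination and Fanconi anaemia, T and NK lineage, type I interferon, and STAT targets and SOCS (adjusted p = 0.0515 each).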

Other observations

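Of the tests weighed here, those for a mislabelled library, the neighbours of Ablim1, a transgene insertion, EGFR-DN replicate 3 alone, mature neutrophils and doxycycline were chosen after the results were seen. The genes named in the next paragraph were chosen after their values were seen.

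Of the 57 genes called without EGFR-DN replicate 3, a few are given here, and no test asked whether they share a function. Lgals1, which encodes galectin-1, had a log2 fold change of 1.43 in that fit (edgeR adjusted p = 0.0153), the signalling adaptor Tyrobp 1.53 (adjusted p = 0.0388), the oxidase subunit Ncf1 1.32 (adjusted p = 0.0388), the granule protease Ctsg 1.46 (adjusted p = 0.0388) and the coagulation factor gene F13a1 1.32 (adjusted p = 0.0441). Selplg, the P-selectin ligand gene, was at 0.63 (adjusted p = 0.0412). On the lower side were Dusp6 at −0.84, Klf6 at −0.62, the gap junction gene Gja1 at −0.88 and the collagen gene Col1a2 at −0.995 (adjusted p between 0.0441 and 0.0455). In the left-out library Lgals1 (16.2 CPM), Tyrobp (11.56), Ctsg (15.6) and F13a1 (5.43) were at or below the lowest EGFR-WT library and Ncf1 (13.4) within the EGFR-WT range, so these values come from 2 of 3 EGFR-DN libraries, whereas Selplg (161 CPM) was above all EGFR-WT libraries. Of 56 such genes tested in all 6 libraries, the left-out library lay on the same side of the EGFR-WT mean in 38 and beyond all EGFR-WT libraries in that direction in 34 (60.7%). Over all tested genes, 57.1% had it on the same side as the other EGFR-DN libraries and 49.0% had it beyond all EGFR-WT libraries on that side, and in 84.3% it lay outside the EGFR-WT range in either direction.

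Among quiescence regulators, which did not move as a list, 2 members passed adjusted over the list alone and went opposite ways. The CDK inhibitor gene Cdkn1a was at 20.2 ± 4.26 CPM in EGFR-DN against 9.97 ± 1.54 in EGFR-WT (log2 fold change 1.02, SE 0.21), and the growth suppressor gene Ndn at 12.4 ± 3.11 against 29.5 ± 8.60 CPM (−1.25, SE 0.27). Both had an edgeR adjusted p of 0.688 to 0.690 over all genes and both passed with DESeq2 (adjusted p = 0.0377 and 0.0181). They were chosen after their values were seen. The proto-oncogene Mycn, chosen in the same way, was at −1.05 with DESeq2 (adjusted p = 0.00276; edgeR adjusted p = 0.642).

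Stem cell and age-associated lists lower and progenitor and granule lists higher form the first pattern. It rests on camera at the preset correlation. With an estimated correlation all 4 calls were lost (camera adjusted p from 0.632 to 0.672), and the HSC identity call was also lost without EGFR-DN replicate 1. Without EGFR-DN replicate 3 the 4 medians kept their direction and the smallest was 0.603 in size, which argues against that library alone as the source. Mature neutrophils would bring S100a8 and S100a9 as abundant transcripts, and neither exceeded 2.73 CPM on average in EGFR-DN. A larger share of less primitive cells inside the sorted gate stays open. Cd34 transcripts had a log2 fold change of 0.387 (SE 0.23) and did not pass (edgeR adjusted p = 0.690). The groups overlapped through EGFR-DN replicate 3, at 378 CPM. EGFR-DN replicates 1 and 2 were at 569 and 534 CPM, above every EGFR-WT library (at most 410 CPM). Without replicate 3 the Cd34 log2 fold change was 0.54 (SE 0.12, edgeR adjusted p = 0.118). A changed share and a changed state of each cell cannot be told apart in bulk RNA. Doxycycline differed in every library and cannot be told apart from the making of the truncated receptor, and the ATF4 list, a response to slowed mitochondrial translation, did not pass (adjusted p = 0.586), so an effect of the truncated receptor stays a hypothesis.

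EGFR-DN replicate 3 is the second pattern. Its deviation from the other EGFR-DN libraries trended with transcript length across 86.5% of tested genes (Spearman rho = 0.358, against 0.00942 between EGFR-DN replicates 1 and 2; genes are not independent replicates). The shortest transcripts had a median deviation of −0.60 and the longest 0.73. A trend with length was predicted for lower RNA quality or more non-polyadenylated RNA in that library. It was met, along with the highest rRNA-like share. A trend of either sign would have met that prediction, so the direction seen was not tested and does not single out either cause. A mislabelled EGFR-WT library is argued against by Egfr at 50.3 CPM. Cells of another type stay open, since the cell type medians went both ways, from −1.01 (neutrophil granule) to 0.575 (endothelial and stromal, upper quartile 1.06), with wide spread within each list. A biological difference of the cells in that library was not tested.

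Ablim1, an actin-binding protein gene chosen after its values were seen, is the third pattern. It was at 303, 393 and 86.7 CPM in EGFR-DN replicates 1 to 3 and at 10.0, 1.20 and 16.2 CPM in EGFR-WT (log2 fold change 4.84, SE 1.00, edgeR adjusted p = 0.672; DESeq2 adjusted p = 0.00306). The Egfr and Ablim1 transcripts had 0 shared 31-base sequences, which argues against shared reads, and 10 tested genes within 1 Mb had a median log2 fold change of 0.0666, which argues against a change of the whole region. A transgene insertion at Ablim1, or transgene sequence counted to it, could account for 392.7 CPM in the library with the most Egfr, and cannot be told apart here from a response to the receptor or to doxycycline.

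With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 is out of reach. The real split gave 1 gene against at most 0 in another split, and 16 lists against at most 14, and in each case 1 split, the real one, gave as many. Every other split also called lists, from 6 to 14. Camera at the preset correlation thus called lists when the groups were mixed. Each mixed split still kept part of any real group difference and had EGFR-DN replicate 3 on 1 side. These splits therefore do not give a rate of false calls. Since 0 of the 16 calls held with an estimated correlation, a call at the preset correlation alone is weak evidence.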
